A study of Rattus norvegicus with 6 samples.

How the data were processed

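Total RNA of nucleus pulposus cells, the cells of the gelatinous core of the intervertebral disc, was extracted with TRIzol from Sprague Dawley rats and sequenced as Illumina libraries, per the labels' protocols. Whether polyadenylated RNA was selected was not given in the sources used here. The 6 samples formed 2 groups of 3: a control group, and a group under cyclic tensile strain, applied by a Flexcell tension system at 18% elongation and 0.2 Hz for 24 h. The treatment text is the same on all 6 samples, so the controls were taken as unstretched only because their class label reads control. No label stated whether replicates came from separate animals or cultures, so the p-values measure only the spread between these samples, which may be technical. No label gave a batch, a harvest time or a clock synchronisation step.

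Each deposited file gave 1 value per gene symbol for 22601 rows. The authors' values were taken as FPKM, fragments scaled to transcript length and to the mapped fragments of the library: they were not whole numbers, summed to between 309497 and 348238 per library, and came with cutadapt 1.9.3, HISAT2 2.0.4, Cuffdiff 2.2.1, Cufflinks and DESeq named in the submitters' processing notes. The order and role of these tools, the annotation and any library scaling were not given in the sources used here. The only genome build in those notes is hg19, a human build. The symbols in the files are rat ones: 85.1% of the 22573 rows used matched a symbol or synonym of the GRCr8 rat gene table, and 1189 symbols named rat olfactory receptors by their Olr prefix. Coordinates were therefore not used here.

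FPKM values keep no read totals, so the depth of the libraries is unknown and no counting interval was computed. Low values (0.003 to 0.06 FPKM) were compared between libraries to look for the worth of 1 fragment. The most frequent ratio between a pair of libraries lay between 0.976 and 1.046, but only 2.9% to 12.7% of the low genes fell within 0.01 log2 units of it, too few to recover whole reads. No pair of libraries shared more than 0% of its values at or above 1 FPKM, so no library was a copy of another.

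In 27 rows the symbol had become a calendar date (such as 2-Mar), as spreadsheet software does to March and Sept gene names, and 2 of these dates occurred more than once. These rows held 0.191% to 0.232% of each library's summed FPKM and were left out of the tests. In 1 further row the name and value had run together in 1 control file, and it was left out too.

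Genes with a mean of at least 1 FPKM over the 6 samples were tested (10180 genes), after adding a pseudocount of 1 and taking log2. limma 3.58.1 in R 4.3.3 fitted strain against control with a mean-variance trend and robust moderation. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and all tests were two-sided. Fold changes given as log2 are on the log2(FPKM + 1) scale, which understates the change of low genes. Folds given without log are ratios of the 2 group means of the authors' FPKM and are left out where a group mean is under 1.

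The tests, the alternatives, the rule for named genes and 41 gene lists were fixed before the data were examined, except where said otherwise. The lists covered the clock, disc matrix, proteases, inflammation, stress, metabolism, mechanical signalling, other cell types and RNA quality. Lists with at least 5 tested members (35) were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over lists. They were also tested with camera at an estimated correlation and with fry, whose directional p asks whether a set's genes move one way on balance and whose mixed p asks whether they change in either direction. Neither fry p compares the set with other genes. With an estimated correlation 0 lists passed camera after adjustment (4 had an unadjusted p under 0.05), while 17 passed with the preset correlation and 24 passed directional fry. The adjusted p with an estimated correlation is given beside each list that passed. The power of that test for lists was not measured, so a high value does not show that a list was unchanged.

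The rule for named genes takes every tested core clock gene. It takes the 10 largest rises and 10 largest falls among called genes with at least the median expression (8.03 FPKM), groups that do not overlap and a symbol that is not provisional. It takes the 4 members with the smallest p of each list that passed, and of the cartilage matrix and protease lists in any case. Other genes in the results were chosen after their values were seen. Some genes that the rule takes, and 1 of the lists, are not reported here. The genes outside the rule are Bcl3, Klf2, Gpx1, Cdh2, Egr1, Chst11, Acan, Col2a1, Sox9, Mcm4, Atp5a1, the further proteases that rose, the clock genes under the filter, and the markers of other cell types.

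On simulated data for this comparison (10180 genes with the real means and spreads, 200 changed, 20 runs), the fit recovered 56.8% of genes changed 1.5-fold, 88.2% of those changed 2-fold and 99% of those changed 4-fold. These folds were set on the log2(FPKM + 1) scale. On average 4.2% of the fit's calls were unchanged genes. Of lists without a change, 0.7% had a camera p under 0.05, and 0.1% with an estimated correlation. The simulated genes varied independently of each other, so these rates do not cover lists whose genes move together. Changed genes were not drawn from the lowest-expressed genes, so the recovery does not apply to those. The 200 changed genes are also far fewer than the 3608 called in the real data.

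The alternatives were the replicate number as a block, each sample left out in turn, a pseudocount of 0.1, no filter, a filter at a mean of 5 FPKM, median-ratio rescaling and quantile normalization. Stricter thresholds were tried too. A fit without the trend and robust moderation, and one that kept the date-named rows, were added after the data were seen.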

Results

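Gene expression was measured by RNA sequencing in rat nucleus pulposus cells, 3 control libraries and 3 libraries of cells under cyclic tensile strain (18% elongation, 0.2 Hz, 24 h). The comparison asks how such stretching changes the transcriptome and, as the series' design states, the genes of the circadian clock. Between 14399 and 14605 rows per library had a value above 0, and between 10068 and 10142 reached 1 FPKM. The 10 most abundant genes took 12.1% to 13.8% of each library's summed FPKM. Pearson correlations of log2 values across genes were 0.9883 to 0.9905 within the control group, 0.9825 to 0.992 within the strain group and 0.9206 to 0.9597 between the groups. The first principal component held 78.6% of the variance and separated the groups, with controls at -32.7 to -24.1 and strain libraries at 20.6 to 35.9. Strain replicate 1 lay nearest to the controls on it, and strain replicate 3 stood apart from the other strain libraries on the next component (17.5 against -9.7 and -10.8).

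Strain was accompanied by changes in 3608 of 10180 tested genes, of which 1672 were higher and 1936 lower (limma, adjusted p under 0.05). The 10 largest falls among the named genes included cytokines and the matrix-degrading enzymes Mmp9 and Mmp10, and the 10 largest rises included Thbs4, Col6a3 and Col3a1 of the extracellular matrix. At least a 2-fold change on the log2(FPKM + 1) scale, not as a ratio of FPKM means, was reached by 209 higher and 383 lower genes. The groups did not overlap in 51.9% of tested genes, where chance gives 10%. After quantile normalization the balance turned, with 2138 genes higher and 1711 lower. Without control replicate 1 the count was 2375 genes, of which 1047 were higher. The median log2 fold change of all tested genes was -0.0123.

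Of the 20 core clock genes fixed beforehand, 16 were expressed above the filter, and 6 of these fell, 1 rose and 9 were not called. Nr1d2 and Nr1d1, which encode the REV-ERB repressors of the clock, fell from 13.02 ± 1.55 to 6.45 ± 0.89 FPKM and from 17.7 ± 3.05 to 11.1 ± 1.67 FPKM (SD, n = 3; adjusted p = 0.00073 and 0.010 by limma). Per1, a period gene of the negative limb, fell 1.52-fold to 2.42 ± 0.48 FPKM, and the clock output factor Tef fell 1.40-fold to 3.72 ± 0.45 FPKM. Npas2, a partner of BMAL1, fell 1.26-fold, and Rora, an activator of Bmal1 transcription, fell 1.39-fold. Dbp, another output factor of the same family as Tef, rose 1.72-fold, from 5.63 ± 0.38 to 9.67 ± 3.10 FPKM, with strain replicate 1 (6.26 FPKM) close to the highest control (5.91 FPKM).

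Arntl, which encodes BMAL1, stood at 9.06 ± 1.88 FPKM in controls and 8.80 ± 0.15 FPKM under strain (log2 fold change -0.02 ± 0.13 SE). Per2 was at 1.103 ± 0.18 and 1.09 ± 0.13 FPKM, Nfil3 at 12.1 ± 2.57 and 11.8 ± 0.73 FPKM, and Cry2 at 6.03 ± 0.36 and 6.45 ± 0.11 FPKM. Clock (8.14 ± 0.76 and 6.41 ± 1.26 FPKM), Bhlhe40 (40.5 ± 9.16 and 31.8 ± 2.38 FPKM) and Bhlhe41 (2.23 ± 1.54 and 1.39 ± 0.07 FPKM) did not pass either. By limma, Cry1 and Ciart passed when adjusted over the list alone (adjusted p = 0.041 and 0.046) and not over all genes (0.055 and 0.066). Ciart was at 4.89 and 5.04 FPKM in control replicates 1 and 2 but at 1.32 FPKM in control replicate 3, near the strain mean of 1.19 ± 0.10 FPKM. Below the filter, Per3 averaged 0.944 ± 0.130 FPKM in controls and 0.590 ± 0.160 FPKM under strain, Rorb 0.556 ± 0.148 and 0.186 ± 0.082 FPKM, and Hlf under 0.05 FPKM in every library.

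For the list as a whole, 7 members passed over all genes and 9 adjusted over the list alone. The mixed fry test in limma gave an adjusted p = 0.0013 over lists (0.00106 before adjustment). That p does not set the list apart from other genes, since 3608 of all 10180 tested genes were called. Heat shock chaperones, a list that camera did not call, had a mixed fry adjusted p = 0.00095. Camera placed the core clock list lower under strain at the threshold (median log2 fold change -0.32, adjusted p = 0.049), with adjusted p = 0.54 with an estimated correlation. The E-box-driven arm had 4 falls (Nr1d1, Nr1d2, Per1 and Tef) and 1 rise (Dbp) among 10 members (camera adjusted p = 0.13; adjusted over the list alone 5 and 1), and the arm driven by ROR and REV-ERB had 1 fall, Npas2, among 5 (adjusted p = 0.33; 0 adjusted over the list alone). The count of 7 depended on single libraries: 3 genes were called without control replicate 1 or control replicate 2, 2 without strain replicate 2 and 4 without strain replicate 3. Camera no longer called the list without control replicate 1, control replicate 2, strain replicate 1 or strain replicate 3 (adjusted p = 0.0621, 0.154, 0.0844 and 0.0814), nor with a filter at 5 FPKM (0.43; 0.00479 to 0.43 over 14 alternatives), whereas the mixed p stayed between 4.79e-05 and 0.00716 with each library left out. Nr1d1 and Nr1d2 were called in all 14 alternatives, while Npas2 lost its call in 9 of 14, Dbp in 6 of 14, Rora in 5 of 13, Tef in 4 of 13 and Per1 in 2 of 13.

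**Figure D1:**
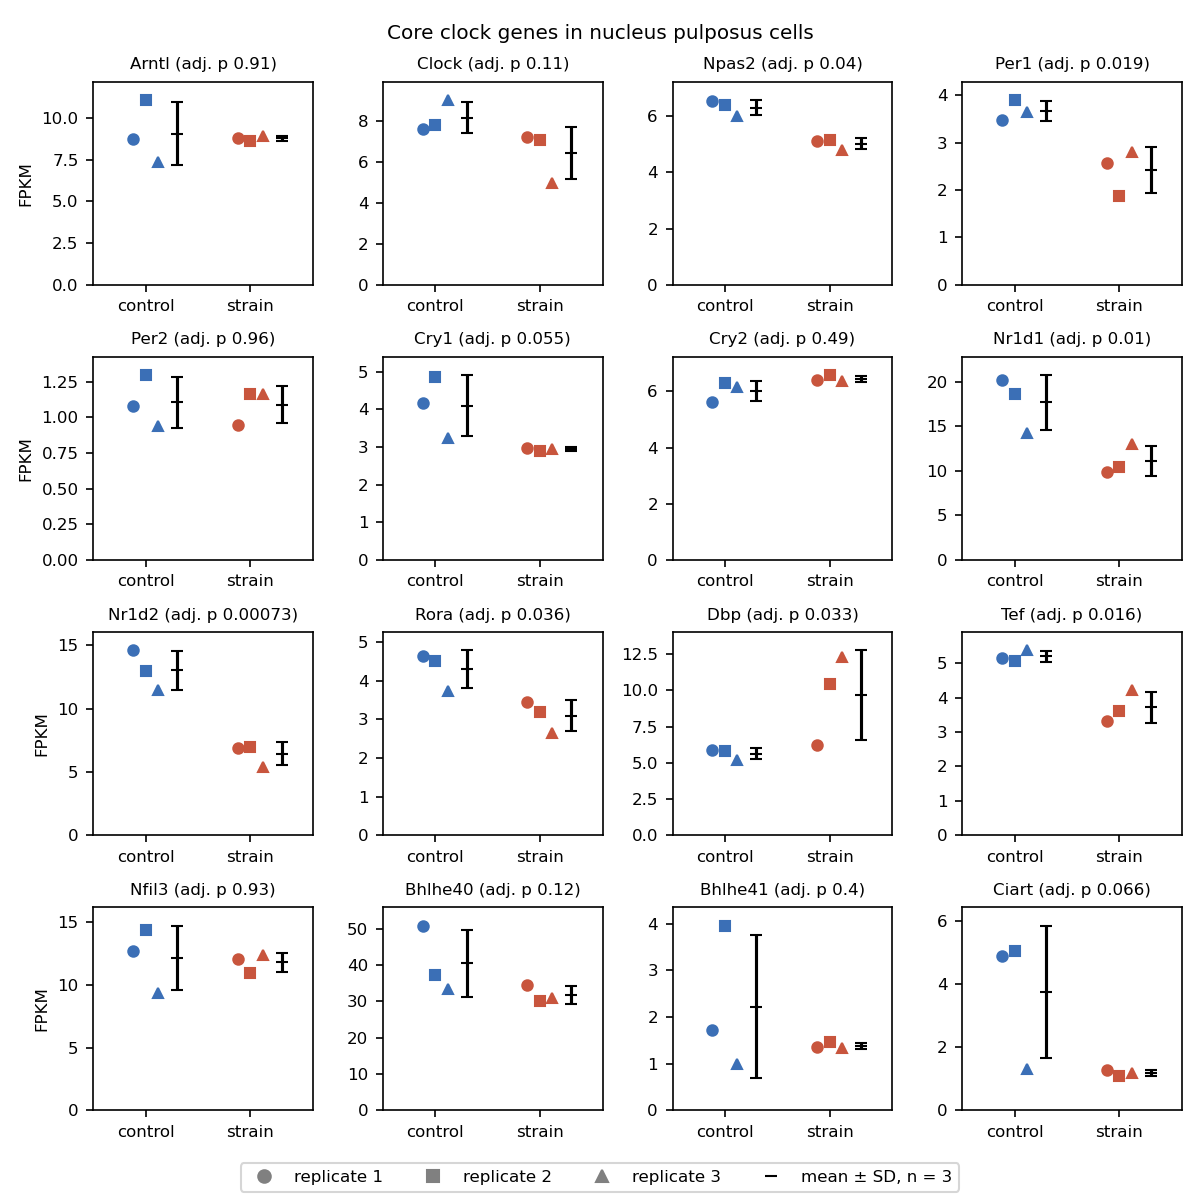
FPKM of the 16 tested core clock genes per library (y axis, linear from 0) in control and strain cells (x axis), with marker shapes for replicate numbers and a bar for the mean ± SD of 3 libraries. Nr1d1, Nr1d2, Per1 and Tef lie lower in all 3 strain libraries, Dbp lies higher with a wide spread, and the groups overlap for Arntl, Per2 and Nfil3.

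Among 20 tested genes that modify clock proteins or their activity, 7 fell and 0 rose (camera adjusted p = 0.019; the same counts adjusted over the list alone). Nampt, which encodes the rate-limiting enzyme of the NAD salvage pathway, fell 2.51-fold to 19.8 ± 2.45 FPKM. The NAD-dependent deacetylase gene Sirt1 fell 1.73-fold, the ubiquitin ligase component Fbxw11 1.49-fold and the RNA-binding protein gene Sfpq 1.41-fold. The list had adjusted p = 0.37 with an estimated correlation, and camera no longer called it with a filter at 5 FPKM (adjusted p = 0.0563; 0.00607 to 0.0563 over 14 alternatives).

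Genes that respond to NF-kB, a transcription factor of inflammatory signalling, formed the list with the strongest change: 25 of 26 tested members fell, with a median log2 fold change of -2.54 (camera adjusted p = 3.13e-15; adjusted p = 0.37 with an estimated correlation; 25 adjusted over the list alone). The chemokine Ccl3, chosen as 1 of the 10 largest falls, dropped from 543 ± 156 to 4.22 ± 4.05 FPKM. The colony-stimulating factors Csf2 and Csf3 dropped from 361 ± 79.8 to 6.61 ± 6.64 FPKM and from 760 ± 224 to 15.0 ± 12.7 FPKM, and Csf1 fell 3.31-fold. The cytokines Il1a and Il23a dropped from 228 ± 32.9 to 8.09 ± 7.86 FPKM and from 104 ± 29.9 to 2.01 ± 2.73 FPKM. Strain replicate 1 set much of these strain means: without it they were 1.88 FPKM for Ccl3, 2.77 for Csf2, 7.70 for Csf3, 3.60 for Il1a and 0.430 for Il23a. Ccl5 dropped from 41.0 ± 7.36 to 0.357 ± 0.076 FPKM, Tnfaip6 fell 5.37-fold and Nfkb2, a subunit of NF-kB itself, 4.98-fold. The 1 member that rose was Bcl3, a nuclear regulator of NF-kB, from 3.25 ± 0.48 to 7.20 ± 1.85 FPKM. Mean log2 expression of the list was 7.79 to 8.10 in controls, 5.78 in strain replicate 1, and 4.998 and 4.879 in strain replicates 2 and 3.

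Of 20 macrophage markers, 4 were expressed above the filter, and they moved apart: Adgre1 fell from 3.71 ± 1.92 to 1.31 ± 0.10 FPKM and Cd68 from 1.53 ± 0.42 to 0.633 ± 0.147 FPKM. Lyz2 rose from 0.249 ± 0.142 to 3.30 ± 1.62 FPKM, and Cd14 (14.5 ± 1.26 and 15.8 ± 0.30 FPKM) was not called. The pan-leukocyte gene Ptprc stayed at a mean of 0.005 FPKM in controls and 0.023 FPKM under strain. None of 16 blood cell markers in the files passed the filter. Only 2 of 16 endothelial markers passed the filter, of which Eng rose. Only 2 of 15 neural and Schwann markers passed it, S100b and Tubb3, and both rose. Of 16 skeletal muscle markers 2 passed it, and neither was called. Under the filter, limma without a filter called the endothelial marker Flt1 lower (1.43 ± 0.23 to 0.484 ± 0.017 FPKM). It called the endothelial markers Pecam1 (0.069 to 0.269 FPKM) and Erg (0.022 to 0.080 FPKM) higher. None of the 13 mitochondrially encoded genes was matched by symbol.

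Immediate-early genes, transcription factors and regulators induced within minutes of a stimulus, were lower as well, with 14 falls and 1 rise among 21 (camera adjusted p = 5.43e-05; 0.44 with an estimated correlation; 15 and 1 adjusted over the list alone). Ier3 fell 7.19-fold, Fosl1 3.05-fold, Jun 2.56-fold and Ier5 2.11-fold, and the 1 rise was Klf2. Glucocorticoid-responsive genes had 7 falls among 12 (adjusted p = 0.0048; 0.44 with an estimated correlation; 8 adjusted over the list alone), among them the EGFR inhibitor Errfi1 (3.57-fold), the kinase Sgk1 (2.52-fold), the glucocorticoid receptor Nr3c1 (1.77-fold) and the phosphatase Dusp1 (1.63-fold). Dusp1 also counts among the immediate-early genes and Per1 among the clock genes.

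Matrix-degrading enzymes divided into a group that fell and a smaller group that rose, 11 and 5 of 22 both over all genes and adjusted over the list alone (camera adjusted p = 0.033; 0.45 with an estimated correlation). The stromelysins Mmp3 and Mmp10 dropped from 5518 ± 1416 to 301.5 ± 154 FPKM and from 985 ± 271 to 21.3 ± 15.8 FPKM. The gelatinase Mmp9 dropped from 520 ± 171 to 8.08 ± 6.70 FPKM, Mmp12 from 40.1 ± 17.6 to 0.395 ± 0.338 FPKM, and the aggrecanase Adamts4 5.37-fold to 4.97 ± 0.34 FPKM. Ctsk, the collagenolytic cathepsin K, rose 1.99-fold to 30.5 ± 2.76 FPKM. Without strain replicate 1 the strain means were 4.22 FPKM for Mmp9, 12.2 for Mmp10 and 0.220 for Mmp12. The other rises were Adamts1, Adamts5, Adamts12 and Mmp11. Camera no longer called the list without strain replicate 3 (adjusted p = 0.0614) or without a filter on low values (adjusted p = 0.0565; 0.00663 to 0.0614 over 14 alternatives). Other secreted or metabolic genes among the 10 largest falls were the plasminogen activator inhibitor Serpinb2 (136 ± 39.8 to 2.71 ± 1.85 FPKM), the growth factor binding protein Igfbp5 (326 ± 64.7 to 5.07 ± 3.23 FPKM) and the arginine synthesis enzyme Ass1 (99.9 ± 28.6 to 1.65 ± 1.37 FPKM). Their strain means without strain replicate 1 were 1.70, 3.21 and 0.861 FPKM.

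**Figure D2:**
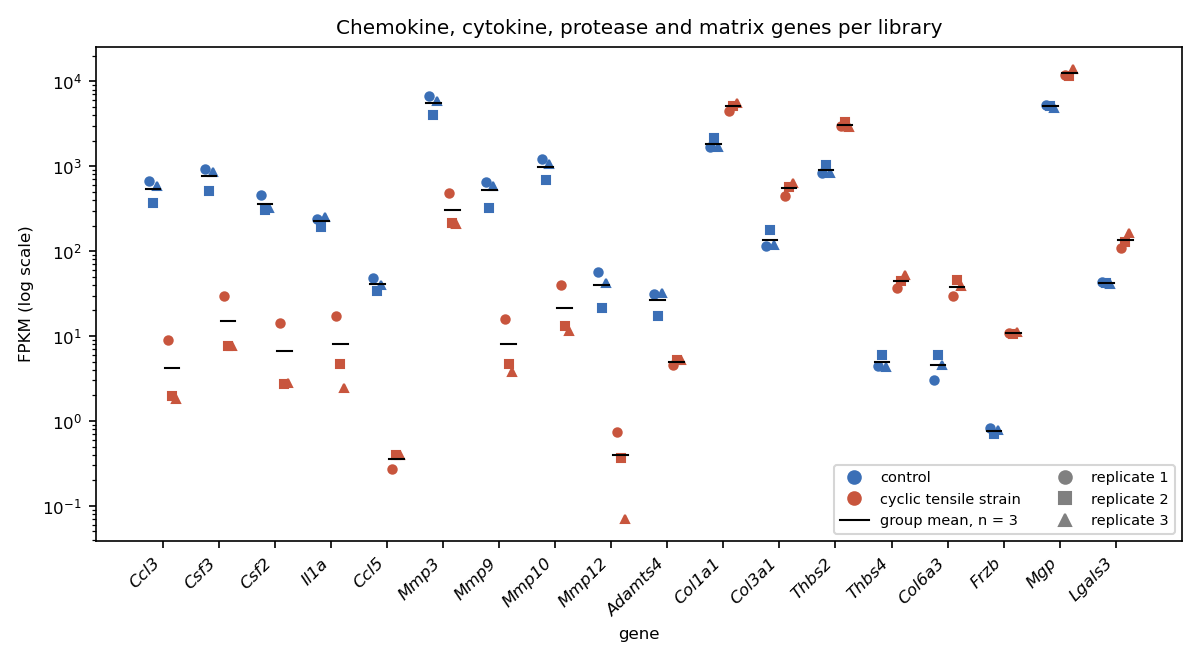
FPKM per library on a logarithmic y axis for named chemokine, cytokine, protease and matrix genes (x axis), with control and strain libraries in different colours and a line at each group mean of 3. Strain libraries lie below all controls for the chemokines, cytokines and proteases, with strain replicate 1 the highest of the strain libraries for Ccl3, Csf2, Csf3, Il1a, Mmp3, Mmp9, Mmp10 and Mmp12, and above all controls for the matrix genes.

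Fibrous matrix genes rose under strain, 14 of 21 with 0 falls (median log2 fold change 0.55, camera adjusted p = 2.12e-06; 0.44 with an estimated correlation; 16 rises and 1 fall adjusted over the list alone). Col1a1 and Col3a1, the main fibrillar collagens of fibrous tissue, rose from 1849 ± 275 to 5085 ± 533 FPKM and from 137 ± 35.03 to 547 ± 91.9 FPKM. The matricellular gene Thbs2 rose 3.39-fold and the collagen cross-linking enzyme gene Loxl2 1.93-fold. Among the 10 largest rises were also Col6a3 (8.41-fold), Olfml2b (3.63-fold), the sulfatase gene Arsi (4.71-fold), Nrep (4.27-fold), Eno3 (4.68-fold), Cox6a2 (4.12-fold) and Net1 (4.12-fold). Markers of tendon and of the annulus fibrosus, the fibrous outer ring of the disc, moved with them: 6 of 11 rose and 1, Egr1, fell (adjusted p = 0.018; 0.37 with an estimated correlation; 6 and 2 adjusted over the list alone). Thbs4 rose 9.07-fold to 44.6 ± 7.29 FPKM, the tendon transcription factor Scx 2.44-fold, and Mkx rose from 0.704 ± 0.060 to 2.47 ± 0.34 FPKM. Col1a1 is in both lists.

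Markers of notochordal and nucleus pulposus cells rose in the same libraries, 10 of 12 tested with 1 fall, Cdh2 (camera adjusted p = 0.00030; 0.37 with an estimated correlation; 10 and 2 adjusted over the list alone). The sclerotome factor Pax1 rose 2.98-fold to 10.3 ± 1.08 FPKM, Lgals3 3.19-fold, Ncam1 2.42-fold, and Mgp, the matrix Gla protein that inhibits calcification, from 5102 ± 195 to 12404 ± 1203 FPKM. Of 21 markers fixed, 20 were in the files and 12 passed the filter. Cartilage and nucleus pulposus matrix genes had 7 rises and 2 falls among 13, also adjusted over the list alone (adjusted p = 0.029; 0.37 with an estimated correlation). Of 28 such genes fixed, 27 were in the files and only these 13 passed the filter. The collagen gene Col2a1 was under it, at 0.042 ± 0.029 FPKM in controls and 0.898 ± 0.485 FPKM under strain. Dcn rose 2.42-fold, Col11a1 2.78-fold, the chondrogenic factor Sox9 1.87-fold, and the link protein gene Hapln1 from 0.251 ± 0.015 to 1.89 ± 0.36 FPKM. Xylt1, which starts glycosaminoglycan chains, fell 5.31-fold, and Chst11 fell too. The aggrecan gene Acan was at 31.1 ± 10.6 FPKM in controls and 38.6 ± 3.18 FPKM under strain and was not called (adjusted p = 0.20). Wnt pathway genes had 9 rises and 1 fall among 16 (adjusted p = 0.0099; 0.37 with an estimated correlation; 9 and 2 adjusted over the list alone). Frzb, a secreted Wnt antagonist, rose from 0.772 ± 0.064 to 10.8 ± 0.30 FPKM, the connective tissue factor Wisp2 5.07-fold and the receptor Fzd2 2.31-fold, whereas the ligand Wnt5a fell 4.15-fold.

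Cholesterol synthesis genes fell in 19 of 21 tested cases, with 0 rises (median log2 fold change -1.22, camera adjusted p = 1.56e-12; 0.37 with an estimated correlation; 19 adjusted over the list alone). The pathway enzymes Hmgcs1, Idi1 and Hsd17b7 fell 3.68-fold, 4.47-fold and 4.62-fold. Antioxidant genes under NRF2 had 13 falls and 1 rise, Gpx1, among 21 (adjusted p = 1.85e-05; 0.45 with an estimated correlation; 14 and 1 adjusted over the list alone). The cystine transporter gene Slc7a11 fell 21.1-fold to 1.80 ± 0.36 FPKM, Nqo1 6.11-fold, Txnrd1 3.65-fold and Gclc, the rate-limiting enzyme of glutathione synthesis, 3.58-fold. Genes of the unfolded protein response, the chaperone programme of the endoplasmic reticulum, had 12 falls among 19 (adjusted p = 0.00045; 0.45 with an estimated correlation; 12 adjusted over the list alone). Sdf2l1 fell 1.80-fold, Hspa5 1.58-fold, Hsp90b1 1.53-fold and Dnajc3 1.39-fold.

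Cytosolic ribosomal protein genes were higher in 15 of 39 tested cases with 0 falls (median log2 fold change 0.35, camera adjusted p = 1.87e-06; 0.56 with an estimated correlation, fry adjusted p = 0.070; 27 rises adjusted over the list alone). Rplp0 rose 1.38-fold and Rps19 1.30-fold. Mean log2 expression of the list was 8.04 to 8.14 in controls, 8.31 and 8.26 in strain replicates 1 and 2, and 8.62 in strain replicate 3. Genes of oxidative phosphorylation had 4 rises and 1 fall among 30, and 0 of either adjusted over the list alone. Camera gave an adjusted p = 0.045 (0.73 with an estimated correlation), and directional fry gave an adjusted p = 0.31. Mean log2 expression of the list was 5.92 to 5.97 in controls. It was 5.99 and 5.98 in strain replicates 1 and 2, and 6.25 in strain replicate 3. Ndufs3 rose 1.41-fold, Atp5o 1.32-fold and Atp5c1 1.24-fold, the other rise was Atp5a1, and the cytochrome c gene Cycs fell 1.24-fold. Camera no longer called this list without strain replicate 3 (adjusted p = 0.22) or control replicate 2 (adjusted p = 0.14; 0.0039 to 0.22 over 14 alternatives). The calls of these named ribosomal and oxidative phosphorylation genes were lost in at least 1 alternative.

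S-phase genes had 5 falls among 22, and 4 adjusted over the list alone. Camera gave an adjusted p = 0.039 (0.56 with an estimated correlation), and directional fry gave an adjusted p = 0.076. The replication clamp gene Pcna fell 1.53-fold, and Mcm3, Rrm2 and Fen1 fell 1.598-fold, 1.56-fold and 1.47-fold, and the other fall was Mcm4. Without control replicate 2 or strain replicate 1, or with a filter at 5 FPKM, the list was not called (adjusted p = 0.169, 0.101 and 0.269; 0.0075 to 0.269 over 14 alternatives). Of 26 G2/M-phase genes, 0 were called by limma in either direction, over all genes or adjusted over the list alone. By limma, 2 had an unadjusted p under 0.05. The list had a camera adjusted p = 0.42 and a fry mixed adjusted p = 0.48. Its mean log2 expression was 2.76 in control replicate 2 and 2.19 and 2.11 in control replicates 1 and 3. Under strain it was 2.23 to 2.27.

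**Figure D3:**
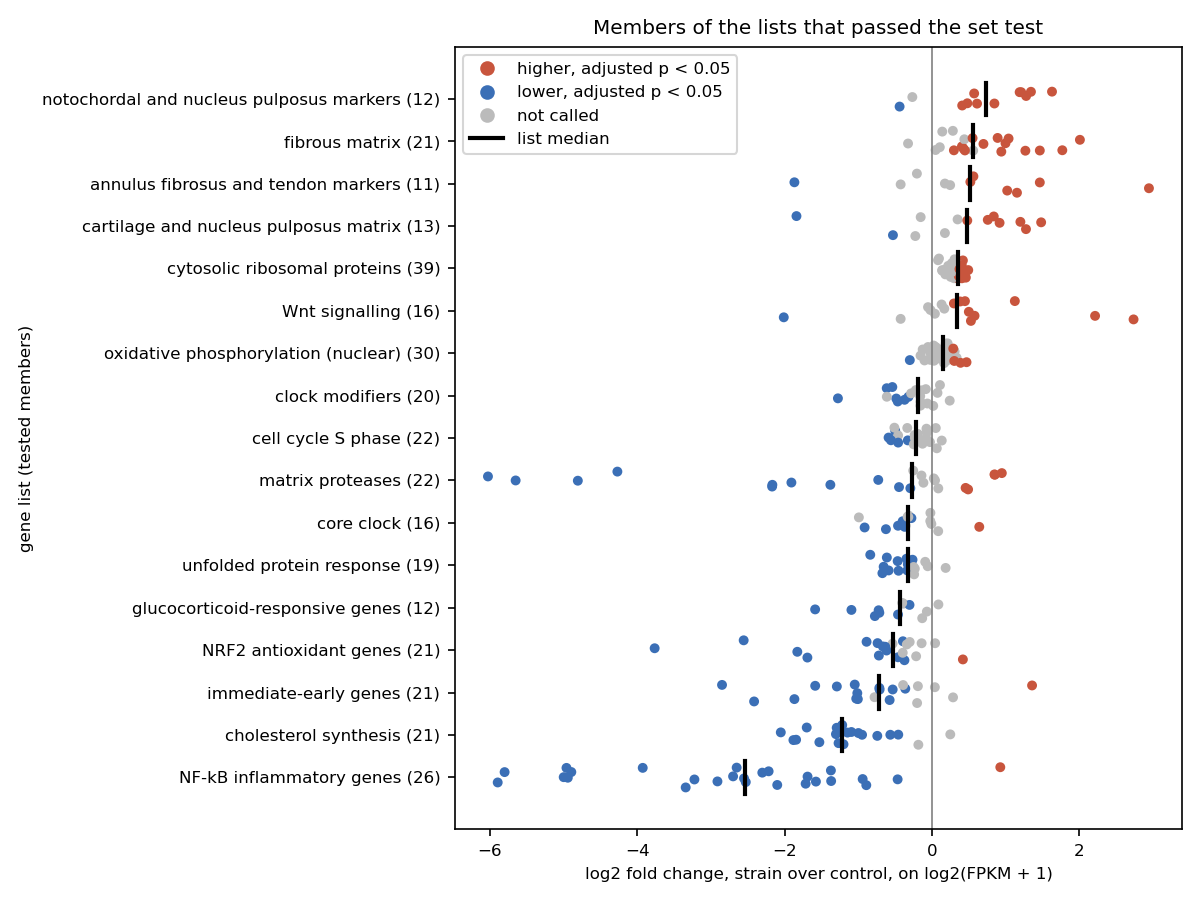
Log2 fold change of each tested member (x axis, strain over control on log2(FPKM + 1)) for the 17 lists that passed camera (y axis, number of tested members in brackets), coloured by call, with a black line at the list median. Medians run from -2.54 for NF-kB inflammatory genes to 0.73 for notochordal and nucleus pulposus markers.

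Lipid, senescence, adhesion and stress genes were in lists that did not pass camera, 18 of the 35 tested with the clock arms and G2/M genes included. Lipid and adipogenic genes had 7 falls and 2 rises among 12 (adjusted p = 0.051), and p53 and senescence genes 10 falls and 1 rise among 22 (0.055). Mechanosensing ion channels had 3 rises and 1 fall among 8 (0.33), apoptosis genes 2 rises and 6 falls among 22 (0.33), and TGF-beta and BMP genes 7 rises and 8 falls among 23 (0.34). Integrin and focal adhesion genes had 3 rises and 5 falls among 19, protease inhibitors 2 and 4 among 9, and interferon-stimulated genes 2 and 5 among 14 (0.40 each). YAP/TAZ targets, a read-out of mechanical signalling, had 5 rises and 4 falls among 21 (0.40). Integrated stress response genes had 2 rises and 3 falls among 21 (0.61), hypoxia and glycolysis genes 5 and 6 among 27 (0.67), autophagy and lysosome genes 2 and 2 among 22 (0.78) and heat shock chaperones 2 and 4 among 13 (0.93). Hypertrophic and osteoblast markers had 2 rises and 1 fall among 5 (0.32). For the hypertrophic, hypoxia and heat shock lists the median, mean and camera direction differed in sign. Adjusted over the list alone, ion channels had 3 rises and 2 falls, apoptosis genes 3 and 6, TGF-beta and BMP genes 7 and 10, protease inhibitors 3 and 4, and YAP/TAZ targets 6 and 4. The lipid, p53, integrin, interferon, integrated stress response, hypoxia, autophagy, heat shock and hypertrophic lists kept the counts given here. Without control replicate 3 the integrated stress response list passed (adjusted p = 0.00377; 0.00377 to 0.984 over 14 alternatives), as did the E-box list (0.0243; 0.0243 to 0.534). The p53 list passed in 4 of 14 alternatives (0.00479 to 0.107) and the lipid list in 7 (0.0267 to 0.12). In control replicate 3 the mean log2 expression of the integrated stress response list was 4.96. It was 5.90 and 6.01 in control replicates 1 and 2, and 5.18 to 5.43 under strain.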

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

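The tests of library scaling, leukocytes, label errors and clock phase, and the fit that kept the date-named rows, were chosen only after the result was seen. The tests without strain replicate 3 and the count over splits of the samples were set out before their results were seen.

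Some rows outside the comparisons were also called, in both directions. Of 16 rows with a date in place of a gene symbol and a mean of at least 1 FPKM, 3 were called higher and 1 lower when these rows were kept in the fit. Among 5972 genes under the filter, 330 were called higher and 344 lower by limma without a filter. No group was large enough for a test of single samples far from the rest.

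NF-kB inflammatory genes lay far lower in the libraries labelled strain, and the tables argue against 3 technical explanations. Quantile normalization left the list's median log2 fold change at -2.49, against library scaling as the cause. Only 3 of 20 macrophage markers averaged 1 FPKM or more in controls, with Ptprc at 0.005 FPKM, against many leukocytes in those libraries. Of these 3, Adgre1 and Cd68 fell under strain and Cd14 was not called, so a small share of such cells is not excluded. In addition, 0 libraries lay nearer to the other group's mean profile, against a single wrong label. An exchange of all 6 labels cannot be told apart from an effect of strain, because YAP/TAZ targets, which stretch is known to raise, had a median log2 fold change of 0.146 and did not pass their test. An effect of stretching on inflammatory signalling may therefore be the source, as a hypothesis, and so may any difference between the groups that the labels do not record.

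Core clock genes changed with Nr1d1, Nr1d2, Per1, Tef, Rora and Npas2 lower and Dbp higher. Without strain replicate 3, 7 of the 7 genes kept their direction at an unadjusted p under 0.05, which argues against that library alone as the source of their direction. The 7 genes had been called with that library in the fit, so the test was a lenient one. By limma, Npas2, Rora and Dbp lost their call without it (adjusted p = 0.0531, 0.0788 and 0.0955). A different clock phase at harvest may be a source and cannot be told apart from a change in clock level, because no label gives a harvest time and Arntl, which should move against Nr1d1 in a phase shift, had a log2 fold change of -0.023 with an SE of 0.13. An effect of strain on the clock remains open beside it.

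Cytosolic ribosomal protein genes were higher in the strain libraries, most in strain replicate 3. Without that library the list's mean log2 difference was 0.211 (SE 0.0447) against 0.323 with it, above the bound of 0.161 set for a cause in that library alone. The list's median log2 fold change was 0.37 after median-ratio rescaling and 0.33 after quantile normalization, against 0.35 as deposited. An effect of strain remains open.

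The count of 3608 changed genes was set against the other splits of the 6 samples into groups of 3. Only 1 of the 10 splits, the real one, gave as many, and the highest of the others gave 1 gene. With 10 splits a share under 0.05 cannot be reached. In each other split both groups mix control and strain libraries, so the difference between the labels widens their spread and leaves few calls. Their low counts therefore do not show how many genes a grouping of alike samples would call.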

How the results depend on the processing

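The fits without trend and robust moderation (3579 genes) and with date-named rows (3613) were chosen after seeing the data. The alternatives for counts were not run, because the files hold FPKM. Depth is unknown, so its limits could not be given. A 2-fold minimum on the log2(FPKM + 1) scale left 592 genes (209 higher, 383 lower). An adjusted p under 0.01 by limma left 1991 (846 higher, 1145 lower). With an estimated inter-gene correlation 0 lists passed. A filter at a mean of 5 FPKM, which tests fewer genes, left 1071 higher genes and 4 core clock calls, and turned the medians of the interferon list (0.20) and G2/M list (0.00334). Quantile normalization turned Arntl (0.0367) and Nfil3 (0.0481), neither of them called. Leaving out each library in turn gave 2375 to 3576 genes, 1047 to 1528 higher, and 2 to 6 core clock calls. The lowest gene count came without control replicate 1. Log2 medians or values that turned then ranged from -0.27 to 0.0773 for G2/M, -0.46 to 0.0773 for the integrated stress response and -0.0662 to 0.12 for heat shock. For single genes they ranged from -0.15 to 0.12 for Arntl, -0.0655 to 0.0565 for Per2, -0.18 to 0.10 for Nfil3 and -0.62 to 0.03 for Bhlhe41. The cause was not tested. Of 80 named genes called outside the core clock, 72 kept their call in every alternative that tested them. No list median turned under median-ratio rescaling (3733 genes, 1858 higher and 1875 lower) or quantile normalization (3849, 2138 higher and 1711 lower), although the latter turned the balance of the calls.

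The values showed no pairing by replicate number: same-numbered samples had deviation correlations of 0.033, 0.108 and -0.116, and control replicate 1 correlated best with strain replicate 3 (0.12). With 3 samples per group these correlations cannot tell whether same-numbered samples shared a culture or a day. A replicate block gave 3116 genes (1441 higher, 1675 lower), 7 core clock calls and 19 lists. The mixed p of the core clock by fry in limma was 0.00228 under the replicate block.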

Other observations

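All genes and families here were chosen after their values were seen, and the tests of symbol families were chosen only after the result was seen.

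Homeobox genes mark position along the body axis. Of 8 tested Hoxb genes, 5 rose and 0 fell by limma: Hoxb2, Hoxb3, Hoxb5, Hoxb6 and Hoxb8. Hoxb8 was at 1.03 ± 0.38 FPKM in controls and 3.23 ± 1.15 FPKM under strain (SD, n = 3). In the Hoxc cluster, Hoxc11, Hoxc12 and Hoxc13 rose 1.52-fold, 2.51-fold and 2.09-fold, while Hoxc6 fell 2.35-fold and Hoxc4 fell from 1.38 ± 0.16 to 0.883 ± 0.203 FPKM. Among 149 symbol families with at least 8 tested genes, camera called neither Hoxb (adjusted p = 0.129) nor Hoxc (adjusted p = 0.68) and called 3 families. One of these was Psmd, subunits of the proteasome's regulatory particle, with 8 falls and 0 rises among 14 (adjusted p = 0.0259; adjusted p = 0.95 with an estimated correlation). The Hoxb and Psmd medians kept their sign under median-ratio and quantile rescaling.

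Of 8 tested integrin alpha genes (Itga), 4 fell and 1 rose by limma, and camera did not call the family (median log2 fold change -0.72, adjusted p = 0.104). Itga2 and Itga5 fell, from 13.7 ± 3.26 to 0.442 ± 0.157 FPKM and from 180.5 ± 11.98 to 61.1 ± 6.32 FPKM, while Itga11, a collagen receptor subunit, rose 2.85-fold. Igfbp4 and Igfbp6 rose 6.32-fold and 2.92-fold, while Igfbp5 fell 64.3-fold (102-fold without strain replicate 1). Gdf15, a stress-induced cytokine, fell 34.4-fold to 8.07 ± 3.24 FPKM, and Bmp2 fell 7.21-fold. Within the hypoxia and glycolysis list, Slc2a1, Hk1, Hk2, Vegfa, Egln3 and Adm fell while P4ha1, Car9, Pgk1, Gpi and Pgam1 rose, each called by limma.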
